A study of Arabidopsis thaliana with 6 samples.

How the data were processed

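ChIRP-seq libraries were made from Col-0 seeds, 0.3 g per assay, fixed for 20 min with 1% formaldehyde or 1% glutaraldehyde and captured with biotinylated antisense probes against HID1, with unlabelled probes as the mock control, per the labels. Libraries were sequenced as paired reads of 150 bp, per the labels. Samples were grouped by title into HID1 ChIRP, mock and input, with 2 samples in each group. Replicate 1 of the HID1 ChIRP group is the formaldehyde sample and replicate 2 the glutaraldehyde sample, so cross-linker and library are the same contrast. The series' design text speaks of 3 biological replicates of each genotype and the labels give 2 samples in each group, and whether the samples came from separate seed batches is not given in the sources used here.

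The data analysed are 2 deposited peak lists, 1 for each probe library, with chromosome, start, end and score of each peak. The score is the peak caller's value as the authors deposited it, and it was used to rank or filter peaks within a list. The submitters' processing notes name Bowtie2 2.1.0, MACS 1.4.2 and the TAIR10 assembly. In this version of MACS the score is 10 times the negative log10 of the caller's p-value. The lowest scores in both lists lie at 50, which stands for a caller's p-value of 1e-05. The control used for peak calling, the treatment of duplicate and multiply mapped reads and the read depth are not given in the sources used here. A library sequenced more deeply gives more and weaker calls, and multiply mapped reads decide how peaks in repeated sequence appear. The mock and input libraries were not used here.

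Gene positions came from the RefSeq gene table of assembly TAIR10.1. From background knowledge, its nuclear chromosomes have the coordinates of TAIR10 and the revision concerned the organelles. This was checked on the peaks: on each of the 5 chromosomes the lowest density of formaldehyde midpoints lay 100 to 300 bp outside the edges of protein-coding genes, a position that a shift between the assemblies would have blurred. Printed coordinates are those of the peaks, in TAIR10 and counted from 1. The mitochondrial peak was assigned to no gene. The table has no strand, exons, untranslated regions or sequence. The planned classes of promoter, exon, intron and untranslated region and the planned upstream windows were therefore replaced by 5 classes of peak midpoint, which are protein-coding gene body, noncoding gene body, pseudogene body, within 1 kb on either side of a protein-coding gene, and other intergenic, and by gene windows of 1 kb on either side. The plan had put transposable element genes and pseudogenes in a joint class. The pseudogene class used here is that of the gene table, and whether its entries include transposable elements was not checked. The planned test of GC content was not run for want of sequence. The table gives 0 genes the symbol HID1, and AT2G35747 was taken as HID1 from prior knowledge. Pericentromeric intervals were approximate positions set from memory. The span of a chromosome is the last base reached by a peak or listed gene.

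Peaks of the libraries were shared if they overlapped by at least 1 bp. The number of formaldehyde peaks shared was compared with 100000 rotations of all formaldehyde peaks along each chromosome (one-sided permutation test), and the alternatives with 10000. Class shares of the shared intervals were compared with 100000 rotations (two-sided permutation test, Benjamini-Hochberg over 5 classes). Gene lists, 13 with 193 genes, were compared with 100000 random lists of protein-coding genes matched on gene length in 20 bins (two-sided permutation test, Benjamini-Hochberg over 13 lists). All 193 loci were found, and 189 symbols matched the table. Scores of shared and other peaks and the correlation of scores were tested with 100000 resamples. The threshold was 0.05. Tests of the sharing by rank used 2000 local shifts, and those of gene kinds and gene edges 1000 rotations.

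The grouping, tests, gene lists, intervals and most alternatives were fixed before the data were examined. The genes named are HID1, PIF3 and all ABA biosynthesis genes, then the members of each other list with a shared peak, up to 5 by the lower score. The rule adds the 15 shared peaks whose poorer rank is best, with the genes touched in the body or within 1 kb, and the 5 highest scoring unshared peaks of each library. The noncoding entry AT2G03875 and the pseudogenes AT2G16150, AT1G43763 and AT2G13710 and the protein-coding gene AT1G15330, each within 1 kb of one of the 15, and the genes AT2G13450, AT5G38250, AT5G04705 and AT5G05665, within 1 kb of an unshared peak, complete those named by the rule. The alternatives were a score of 100 or more, 50% reciprocal overlap, midpoints within 200 bp, the 1000 highest scoring peaks, uniform placement, peaks outside the pericentromeric intervals, each library alone, flanks of 500 bp and 2 kb, gene bodies only and Fisher's exact test. Added after the data had been seen were local shifts of up to 100 kb, peaks inside the intervals, sharing by gene, flanks and windows on either side, the correlation without the HID1 locus at either overlap, the tests of differences between the libraries, sharing by rank, gene kinds and gene edges.

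The procedures for peaks were tested on simulated peaks with the numbers and widths of these libraries, placed at random and so without their clustering. With 200 shared peaks planted, the excess over chance was 205. Without planted sharing, 2 of 20 simulations passed the threshold. The gene list test was tried on genes marked at random whatever their length, and 1 of 200 random gene lists passed. This did not test the length matching, and so few genes were marked that few lists could pass. For peaks placed at random within the pericentromeric intervals the ratio of observed to expected sharing was 1.01. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.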

Results

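HID1 is a noncoding RNA of Arabidopsis thaliana, and the study addresses its part in seed germination under the control of phytochrome B, the main red light receptor of plants, through the biosynthesis of abscisic acid (ABA), the hormone that keeps seeds dormant. Chromatin isolation by RNA purification (ChIRP) recovers the DNA bound to an RNA with biotinylated antisense probes, here probes against the full length of HID1. The samples were Col-0 seeds given 5 min of red light and 48 h of darkness. The 6 libraries fall into 3 groups of 2, namely the probe libraries, the mock libraries and the input libraries. Peak lists of the 2 probe libraries were analysed, 1 from seeds fixed with formaldehyde and 1 from seeds fixed with glutaraldehyde, and the mock and input libraries were not analysed here. Each cross-linker has 1 library, so there is no replicate check within a cross-linker, and every permutation p compares peak positions or scores within these libraries. The read depth of the libraries is unknown from the peak lists.

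Ordered by the poorer of their ranks, the peaks at the HID1 locus came first among those found with both cross-linkers. AT2G35747, which prior knowledge and not the gene table identifies as HID1, lay in a formaldehyde peak on chromosome 2 from 15029487 to 15030648 (TAIR10) with a score of 348, rank 23 of 4557 peaks. It also lay in a glutaraldehyde peak from 15028597 to 15030657 with a score of 2149.6, rank 1 of 6306, which was 5.07 times the next highest score of that library, 424. The gene table lists AT2G35747 itself as a small nucleolar RNA. The shared interval also touched the bodies of the protein-coding gene AT2G35750 and of the further small nucleolar RNA entries AT2G08765, AT2G08770 and AT2G35744. A further glutaraldehyde peak, from 15027394 to 15028470 with a score of 277, ended 126 bp before the HID1 peak.

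The formaldehyde library held 4557 peaks, all on the nuclear chromosomes, and the glutaraldehyde library 6306, of which 1 lay on the mitochondrial genome and none on the chloroplast genome. Formaldehyde peaks were wider, with a median of 849 bp (interquartile range 663 to 1114) against 630 bp (568 to 782), and both lists covered similar lengths, 4.37 Mb or 3.67% and 4.44 Mb or 3.72% of the nuclear span. Median scores were 74.3 and 72.3. Scores of 100 or more were held by 1224 formaldehyde peaks (26.9%) and 1438 glutaraldehyde peaks (22.8%).

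Around the centromeres the libraries differed. Of the formaldehyde peaks, 34.96% had their midpoint in the pericentromeric intervals, which make up 26.1% of the span, and 17.2% of the glutaraldehyde peaks did. The share lay above that of the span in the formaldehyde library and below it in the glutaraldehyde library on each of the 5 chromosomes, with 42.4% and 20.6% against 30.97% on chromosome 2. Against rotation of the peaks along each chromosome the ratios of observed to expected were 1.32 and 0.661 (two-sided permutation p = 2e-04 for both, the smallest that the rotations can give). The difference of 17.72 percentage points lay outside the 95% range under rotation, -5.44 to 6.69 (two-sided permutation p = 2e-04, the smallest possible). This difference was tested after the profiles had been seen.

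**Figure D1:**
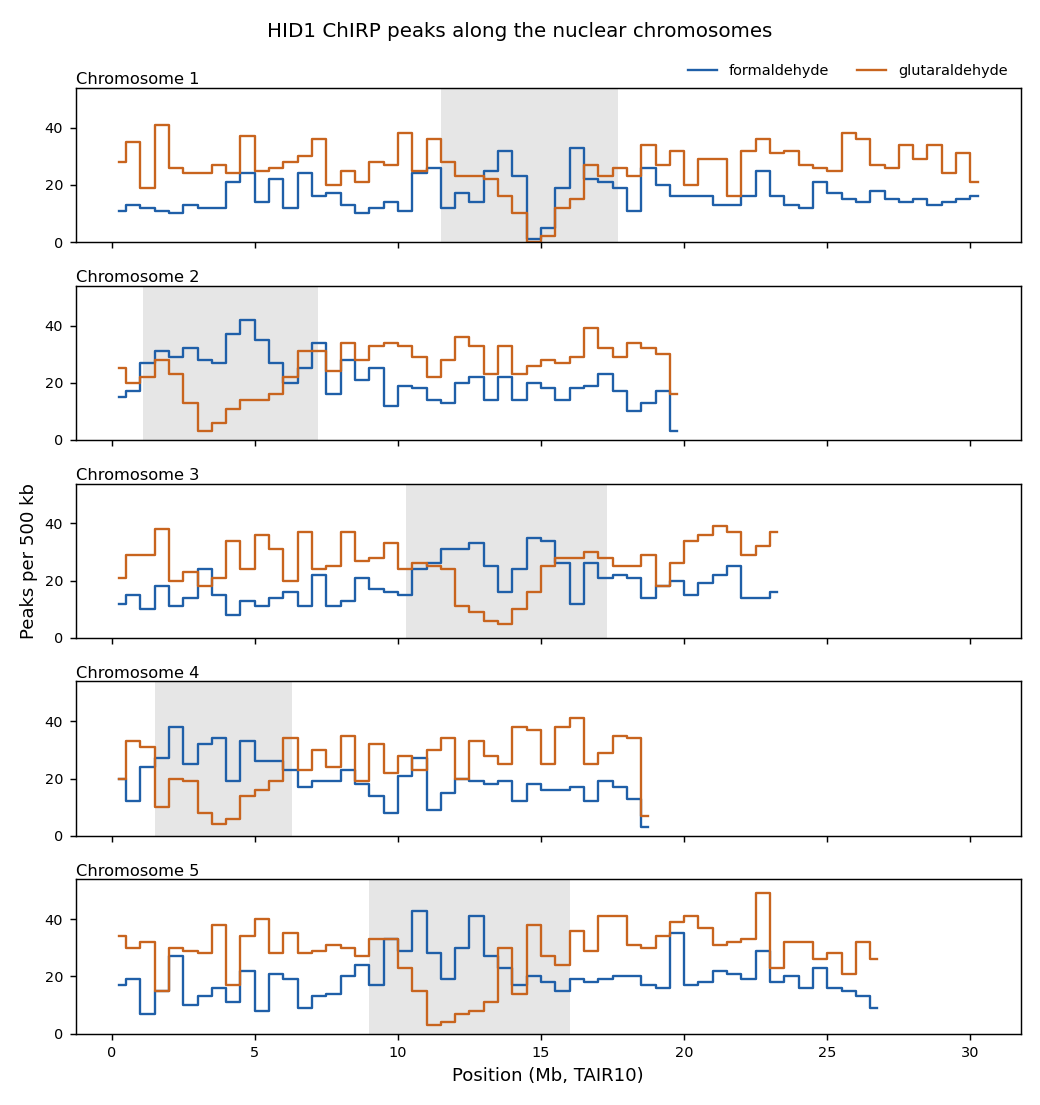
Peaks per 500 kb bin (vertical axis) along the 5 nuclear chromosomes (horizontal axis, Mb, TAIR10) for the formaldehyde and glutaraldehyde HID1 ChIRP libraries, with the pericentromeric intervals shaded and the last bin of each chromosome shorter than the others. The intervals hold 34.96% of the formaldehyde peaks and 17.2% of the glutaraldehyde peaks.

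To find sites recovered with both cross-linkers, peaks that overlapped by at least 1 bp were counted as shared. Of the formaldehyde peaks, 473 (10.4%) overlapped a glutaraldehyde peak, and 483 glutaraldehyde peaks (7.66%) overlapped a formaldehyde peak, in 488 pairs. Rotation gave 391 shared formaldehyde peaks on average (95% range 353 to 429), so the observed number was 1.21 times chance (one-sided permutation p = 2e-05). Inside the pericentromeric intervals 162 formaldehyde peaks were shared against 92.7 expected (ratio 1.75, permutation p = 1e-04, the smallest possible), and outside them 311 against 279 (ratio 1.12, permutation p = 0.0181). The difference between these ratios was not tested, and the count inside the intervals was added after the data had been seen. Among peaks with a score of 100 or more in both libraries, 48 formaldehyde peaks were shared against 30.8 expected (ratio 1.56, permutation p = 0.0022).

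**Figure D2:**
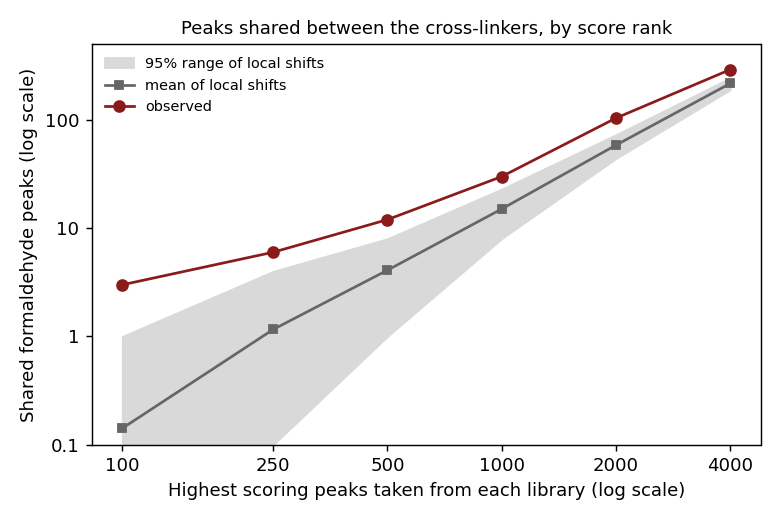
Formaldehyde peaks shared with the glutaraldehyde library (vertical axis, log scale) when the 100 to 4000 highest scoring peaks are taken from each library (horizontal axis, log scale). Points are observed counts, squares the mean and the grey band the 95% range after moving formaldehyde peaks by up to 100 kb, with lower bounds of 0 drawn at the foot of the axis. At 100 peaks 3 were shared against 0.142 expected, and at 4000 peaks 292 against 217. The 3 include the HID1 locus, and the others lay on chromosome 2 from 9471 to 10595 and from 7007926 to 7008649. Sharing was not counted without the HID1 locus.

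After the HID1 locus, the shared peaks that ranked best in both libraries lay at protein-coding genes and at pseudogene entries. The second, on chromosome 2 from 9471 to 10595 with scores of 301 and 325, touched the protein-coding gene AT2G01023, the pseudogene AT2G01022 and the noncoding entry AT2G00340. The next, from 7007926 to 7008649 on chromosome 2 with scores of 346 and 231, touched the pseudogene AT2G16140 and the microRNA gene MIR416. The same formaldehyde peak met another glutaraldehyde peak, with a score of 160, from 7005881 to 7007017. AT1G18830 held a shared peak on chromosome 1 from 6492120 to 6492973 with scores of 209 and 296. The receptor-like kinase genes FRK1 and RKF2 held shared peaks on chromosome 2 from 8328333 to 8329164 and on chromosome 1 from 6590985 to 6591899. CESA9, a cellulose synthase gene, held one on chromosome 2 from 9285608 to 9285895, and TAFII15 and AT4G31715, next to GLR2.4, held one on chromosome 4 from 15353355 to 15354051. The rest of the 15 lay in the bodies of the protein-coding genes AT1G43760, AT2G13720 and AT1G15320 and of the pseudogenes AT3G29771, AT3G43310 and AT1G44510. In all, 10 of the 15 touched a protein-coding gene body, 6 a pseudogene body, and 7 lay in the pericentromeric intervals.

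The highest scoring peaks of a single library lay at different kinds of gene. The 5 of the formaldehyde library lay in or across AT2G13460, AT2G21460, AT2G12920 and AT1G35960, with scores from 447 to 701. The gene table lists these entries as pseudogenes, and whether they are transposable elements was not checked. The highest spanned 5603760 to 5606061 on chromosome 2. The 5 of the glutaraldehyde library, with scores from 340 to 424, lay in the bodies of protein-coding genes. These were AT5G28295 beside NEK3, AT5G23390 with MIA40, AT5G25170 beside CYP71B14, AT5G38260, and BRI1, which encodes the brassinosteroid receptor and had its peak on chromosome 4 from 18325790 to 18326886.

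Against rotation, shared peaks fell into pseudogene entries more often than expected and into the flanks of protein-coding genes less often. Rotation compares the shared intervals with the genome and not with chance overlap of the libraries. Chance overlap alone gave 391 shared formaldehyde peaks on average against 473 observed, and such peaks carry the classes of their own libraries. Whether shared peaks differ in class from chance overlaps was not tested. Of the 488 shared intervals, 18.2% had their midpoint in a pseudogene body against 8.82% expected (ratio 2.07), and 10.5% lay within 1 kb of a protein-coding gene against 19.0% expected (ratio 0.549; permutation with Benjamini-Hochberg adjustment over 5 classes, adjusted p = 5e-05 for both, from the smallest p that the rotations can give). Bodies of protein-coding genes held 57.2% against 53.9% (adjusted permutation p = 0.237), other intergenic sequence 13.3% against 16.9% (adjusted permutation p = 0.0786) and noncoding gene bodies 0.820% against 1.35% (adjusted permutation p = 0.425).

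In each library taken alone, protein-coding gene bodies held more midpoints than chance, 61.4% of the formaldehyde peaks (ratio 1.14, adjusted permutation p = 2.5e-04) and 60.9% of the glutaraldehyde peaks (ratio 1.12, adjusted permutation p = 3.33e-04). Pseudogene bodies held 17.0% of the formaldehyde peaks (ratio 1.93, adjusted permutation p = 2.5e-04) and 5.12% of the glutaraldehyde peaks (ratio 0.595, adjusted permutation p = 3.33e-04), so the direction seen for shared peaks was that of the formaldehyde library and opposite to that of the glutaraldehyde library. Noncoding gene bodies held 1.86% of the glutaraldehyde peaks (ratio 1.38, adjusted permutation p = 0.00125) and 1.51% of the formaldehyde peaks (ratio 1.12, adjusted permutation p = 0.372). Flanks held 7.55% of the formaldehyde peaks (ratio 0.397, adjusted permutation p = 2.5e-04) and 19.3% of the glutaraldehyde peaks (ratio 1.01, adjusted permutation p = 0.664). The shares of the libraries differed for pseudogene bodies and for flanks (adjusted permutation p = 5e-04 for both, from the smallest p that the rotations can give). They did not pass the threshold for protein-coding bodies (adjusted permutation p = 0.761), other intergenic sequence (0.761) or noncoding bodies (0.191). These tests of the difference were added after the shares had been seen.

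**Figure D3:**
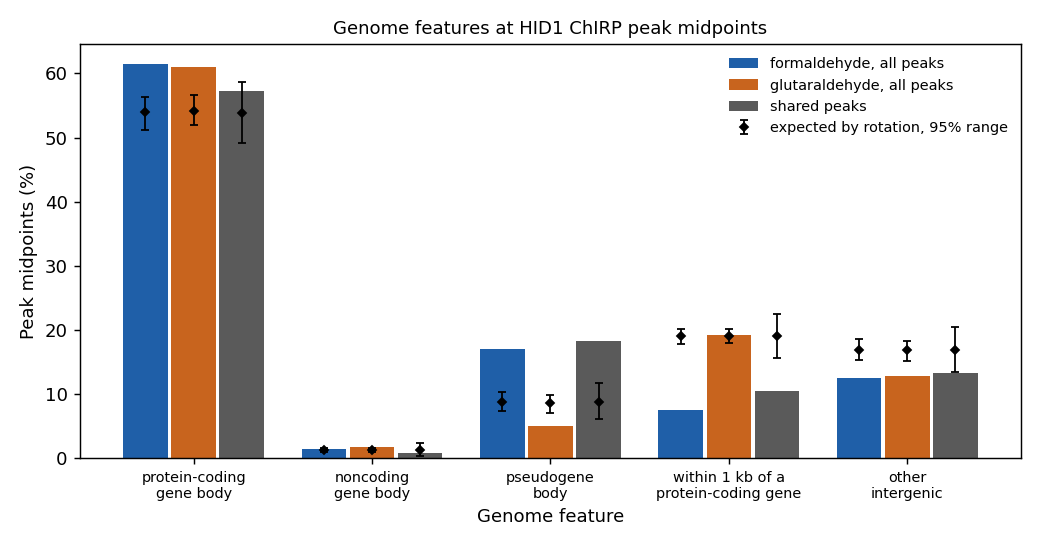
Share of peak midpoints (vertical axis, percent) in 5 genome features (horizontal axis) for all formaldehyde peaks, all glutaraldehyde peaks and the 488 shared peaks. Bars are observed shares, diamonds the mean and whiskers the 95% range under rotation. Pseudogene bodies hold 17.0%, 5.12% and 18.2% of midpoints.

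Among the genes of ABA biosynthesis, NCED9, which encodes a carotenoid cleavage enzyme of the committed step of the pathway, was the gene with a peak in both libraries. The shared interval lay in the gene body on chromosome 1 from 29491952 to 29492779, 828 bp, within a formaldehyde peak from 29491952 to 29492865 and a glutaraldehyde peak from 29491687 to 29492779. The formaldehyde score was 62.8, rank 3097 of 4557, and the glutaraldehyde score 138, rank 586 of 6306, so the NCED9 peak was not shared at a score of 100 or more. Ordered by the poorer of the ranks, the NCED9 pair stood at place 209 of 488. It lay outside the pericentromeric intervals, where chance gave 279 shared formaldehyde peaks on average against 311 observed. A single pair there can therefore be a chance overlap. ABA3, which encodes the molybdenum cofactor sulfurase, had a formaldehyde peak in its body on chromosome 1 from 5662223 to 5663121 with a score of 61.4 and no glutaraldehyde peak. ABA1, VDE1, ABA4, NCED2, NCED3, NCED5, NCED6, ABA2 and AAO3 had no peak in the body or within 1 kb in either library, and neither did PIF3, which encodes a phytochrome-interacting transcription factor. With 1 of 11 genes against 0.208 expected, the number of ABA biosynthesis genes with a shared peak did not pass the threshold against length-matched genes (two-sided permutation p = 0.379, adjusted p = 1 over 13 lists).

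Outside ABA biosynthesis, GA2OX6 and FHL were the listed genes with a shared peak. GA2OX6, which encodes an enzyme that inactivates gibberellin, the hormone that promotes germination, held a shared interval of 222 bp in its body on chromosome 1 from 489256 to 489477 with scores of 87.3 and 89.0. The pair at GA2OX6 was lost when 50% of each peak had to overlap. FHL, which acts in the nuclear import of phytochrome A, had a shared interval within 1 kb on chromosome 5 from 439115 to 439752, 638 bp, with a glutaraldehyde score of 82.3. Neither pair was shared at a score of 100 or more. Both lay outside the pericentromeric intervals, so each can be a chance overlap, as for NCED9.

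Of the 193 genes in the 13 lists, 3 had a shared peak, 22 a formaldehyde peak, 44 a glutaraldehyde peak and 132 no peak. Shared peaks lay at 1 of 19 gibberellin metabolism genes and 1 of 26 phytochrome and light signalling genes. They lay at none of the 4 ABA catabolism, 25 ABA signalling, 9 gibberellin signalling, 16 seed dormancy and maturation, 14 seed storage and late embryogenesis, 11 cell wall expansion, 19 nuclear photosynthesis, 11 circadian clock, 19 chromatin regulator and 9 housekeeping reference genes. By the permutation test with length matching, 0 of 13 lists passed the threshold after adjustment and 0 at an unadjusted p under 0.05, and Fisher's exact test without length matching also gave 0 and 0. Over all 27444 protein-coding genes, 485 (1.77%) had a shared peak within 1 kb, so fewer than 1 gene was expected in each list and a modest enrichment was not detectable.

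At an overlap of at least 1 bp, shared peaks scored slightly higher than the rest. Wider peaks meet such an overlap more easily, and peak width was not accounted for. The median score was 80.6 for shared and 73.6 for other formaldehyde peaks, a difference of 7.02 (two-sided permutation p = 5.2e-04), and 76.1 against 71.9 for glutaraldehyde peaks, a difference of 4.23 (two-sided permutation p = 0.00998). For formaldehyde peaks the difference was -1.38 when 50% of each peak had to overlap (permutation p = 0.599). For glutaraldehyde peaks it was 7.11 under the same rule (permutation p = 0.0072). Across the 488 pairs, which are not independent replicates, the scores of the libraries showed no rank correlation past the threshold (Spearman's rho = 0.0595, permutation p = 0.188). Pearson's r of the log10 scores was 0.0925 (permutation p = 0.0467), and 0.0510 without the HID1 locus (permutation p = 0.264). When 50% of each peak had to overlap, r was 0.265 over 186 pairs (permutation p = 0.00116) and rho 0.124 (permutation p = 0.0925). Without the HID1 locus these were 0.149 (permutation p = 0.0476) and 0.110 (permutation p = 0.135), values added after the data had been seen.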

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

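The tests of differences between the libraries, of local shifts and of the rank of the HID1 peak were chosen after the results had been seen.

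Around the centromeres the libraries moved in opposite directions, with the share of formaldehyde peaks in the pericentromeric intervals 17.72 percentage points above that of glutaraldehyde peaks. Calls close to the peak caller's threshold are argued against as the cause, since 48.1% of formaldehyde peaks with a score of 100 or more lay in the intervals, more than the 34.96% of all formaldehyde peaks. Reads from repeated sequence remain a candidate explanation, since within the intervals formaldehyde midpoints lay in pseudogene entries 1.47 times as often as chance, where glutaraldehyde midpoints did so 0.740 times as often. Whether those entries are repeated sequence was not checked. How multiply mapped reads were treated and what the input library shows in the intervals were not analysed here. Cross-linker and library are the same contrast, and no biological explanation was tested.

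The libraries also differed in genome features. The share of midpoints in pseudogene bodies was 11.9 percentage points higher with formaldehyde, and formaldehyde minus glutaraldehyde was -11.7 percentage points for the flanks of protein-coding genes. The pseudogene difference is not independent of that around the centromeres. Rotation put 27.8% of formaldehyde midpoints within the intervals in pseudogene bodies, and 2.02% of the midpoints of shared intervals outside them. How much of the pseudogene difference this accounts for was not tested. A signal outside the nuclear chromosomes was the mitochondrial glutaraldehyde peak from 232750 to 233540, with a score of 270 and rank 29.

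The libraries shared 1.21 times as many peaks as chance over the genome and 1.12 times on the chromosome arms. Clustering of peaks over regions broader than the shifts is argued against as the whole cause of the genome-wide excess. Moving each formaldehyde peak by up to 100 kb, which keeps regional density, left a ratio of 1.27. The shifts do not keep finer clustering or a preference for the same features. Midpoints of both libraries favoured protein-coding gene bodies (formaldehyde ratio 1.14, glutaraldehyde 1.12), and whether this gives the excess was not tested. Weak calls may account for the small size of the excess on the arms, but this stays open. Arm peaks with a score of 100 or more were shared at 1.499 times chance (26 against 17.34, permutation p = 0.028). This was just under the ratio of 1.5 set for that explanation. Dividing the observed count by the 95% range of the rotations gave 1.0 to 2.6. That range reflects the spread of chance, so it cannot show whether the ratio differs from that of all arm peaks. Both libraries came from wild-type seeds under 1 light condition, and no biological explanation was tested.

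The shared peak that came first by its poorer rank lay at the HID1 locus. Probes complementary to HID1 could also bind the DNA of its own gene there. The peak was rank 1 with glutaraldehyde and rank 23 with formaldehyde, which decides nothing, since direct capture need not outrank every other peak. Capture of DNA and capture of the RNA at its site of transcription cannot be told apart from these lists, since both put a peak at this locus. The mock libraries, which used unlabelled probes per the labels, were not analysed here. HID1 RNA at its own locus stays an untested biological explanation.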

How the results depend on the processing

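The local shifts, sharing inside the intervals, sharing by gene and flanks on either side were chosen after the data had been seen. Sharing stayed above chance with permutation p under 0.05 in all 9 alternatives, with ratios from 1.05 by gene to 1.75 inside the intervals. The test by gene drew genes of similar length as if they were independent. A peak can mark several neighbouring genes, so the p of that test may be too small. No list passed the threshold in any of 6 alternatives. At a score of 100 or more 1224 and 1438 peaks remained. Each library alone gave ratios of 1.12 to 1.14 for protein-coding bodies, 1.12 to 1.38 for noncoding bodies, 0.595 to 1.93 for pseudogene bodies, 0.397 to 1.01 for flanks and 0.740 to 0.761 for other intergenic sequence. Protein-coding and other intergenic classes passed the threshold in both libraries, with 4557 and 6305 peaks in place of 488, as did noncoding bodies with glutaraldehyde, and the direction for noncoding bodies turned in both libraries and for pseudogenes and flanks with glutaraldehyde. At a score of 100 or more, 49 shared intervals gave 0.984 for protein-coding and 1.54 for noncoding bodies, both turned. The noncoding ratio rests on 1 interval, and neither class passed the threshold. Outside the intervals protein-coding bodies reached 1.16 and other intergenic sequence 0.511, and with flanks of 500 bp the latter reached 0.719, all now past the threshold. Formaldehyde scores of shared minus other peaks turned to -1.375 at 50% reciprocal overlap, and the glutaraldehyde difference stayed positive at 7.11. Where no reason is given the cause was not tested. Over all values, 86 alternatives kept the call, 34 moved a count, 7 kept their direction and passed the threshold newly, and 7 turned, of which noncoding bodies with glutaraldehyde also passed it newly. GC content and its alternatives, and windows upstream or downstream of genes, were not run for want of sequence and strand. No paired analysis was possible because peak lists of 1 group only were analysed. Read depth is unknown, so no limit from it can be given.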

Other observations

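The tests of gene kinds and gene edges were chosen after the libraries had been compared.

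Pseudogene entries stood out among the kinds of gene, in opposite directions. Formaldehyde peaks touched the bodies of 759 of 3917 pseudogene entries, 1.59 times chance, and glutaraldehyde peaks those of 300, 0.510 times chance (permutation with Benjamini-Hochberg adjustment over 14 tests, adjusted p = 0.00932 for both). Transfer RNA genes met formaldehyde peaks less often than chance, at 7 of 625 against 24.3 expected (adjusted permutation p = 0.0140), and glutaraldehyde peaks at 20 against 25.9 (adjusted permutation p = 0.454), and the difference between the libraries was not tested. The bodies of protein-coding genes were touched by glutaraldehyde peaks 1.11 times as often as chance (adjusted permutation p = 0.00932) and by formaldehyde peaks 0.960 times as often (adjusted permutation p = 0.213), although formaldehyde midpoints lay in such bodies 1.14 times as often as chance. Small nucleolar RNA, small nuclear RNA, microRNA and long noncoding RNA genes did not pass the threshold in either library.

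Formaldehyde peak midpoints were sparse at the edges of protein-coding genes, with 246 in the 200 bp window at the edges, 595 in that at 500 bp inside and 366 at 1000 bp outside. The density at the edges was 0.413 of that at 500 bp inside, where rotation gave 0.880 to 1.15, and for glutaraldehyde it was 0.823, where rotation gave 0.891 to 1.12 (two-sided permutation p = 0.002 for both, the smallest that 1000 rotations can give). Glutaraldehyde midpoints numbered 600 at the edges, 610 at 1000 bp outside, 729 at 500 bp inside and 591 at 1000 bp inside. That ratio thus went with a higher density near 500 bp inside the genes and not with a dip at their edges. The formaldehyde peaks narrower than the median gave 0.373, so the deficit was not confined to the wider peaks. This does not decide whether peaks that span an edge are the cause. The narrowest formaldehyde peak was 376 bp, still wider than the 200 bp window. No other explanation was tested.

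In the seed dormancy and maturation list, 0 of 16 genes had a formaldehyde peak and 6 had a glutaraldehyde peak, SOM, DAG1, HUB2, CHO1, LEC1 and LEC2, which were named after their values had been seen. Neither library passed the threshold for this list, and the difference was not tested.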
